A study of Mus musculus with 7 samples.

How the data were processed

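Total RNA was extracted with Trizol from livers frozen in liquid nitrogen and labelled for Affymetrix Mouse Gene ST arrays, per the labels' protocols. The deposited table holds 1 value per probe set and array, on a linear intensity scale from 5.41 to 17351, as found from the values. The submitters' processing notes name RMA and Partek for the deposited intensity values, without versions or the role of each. RMA (robust multi-array average) subtracts background, quantile normalizes the arrays and summarises the probes of a probe set. The deposited columns are not equal in distribution, with medians of 105.01 to 110.85 in the knockout and 96.29 to 102.33 in the rescued arrays. RMA normalizes before it summarises, so its columns need not be equal, and what scaling was applied last stays unknown. No detection calls were used here, and control rows could not be told apart in the table, so all 27541 rows were read. No value was missing or at or below 0. The genome build is not given in the sources used here, and no coordinates are printed.

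Groups were taken from the labels. The titles of the rescued arrays call them wild type, while their descriptions name both viruses. The labels call the arrays biological replicates. No pair of arrays shared more than 3.79% of equal values, so none was deposited in duplicate. On the values as deposited, the first principal component held 54.0% of the variance and separated the groups. It put the arrays in the same order as their median intensities, so the offset between the arrays can contribute to this separation.

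Probe sets were named through the platform annotation. Of the rows, 21631 had 1 gene symbol, 1317 several and 4593 none. Of those with 1 symbol, 21544 were matched to the RefSeq gene table of assembly GRCm38.p6 and no symbol had to be updated. A gene was represented by its brightest probe set with exactly 1 symbol, which gave 19933 genes, 951 of them with several probe sets. Log2 was taken first, and no filter on dim genes was applied.

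Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust, two-sided, no covariates), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Of 41 gene lists, 39 with at least 4 measured members were tested with camera at its preset correlation of 0.01. Lists overlap, and list members that the array annotation does not name 1 to 1 were not analysed here. The design, lists and most alternatives were fixed before the data were examined. The alternatives were 3 rescalings of the arrays (quantile, median centring, cyclic loess), 2 filters on dim genes, all rows, mean of probe sets, trend and robust spread, array weights, the replicate number as a block, each array left out, thresholds of 0.01 and 0.1, treat against a fold of 1.2, and other set tests. The count of genes called in every scaling and the filter joined with cyclic loess were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.

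The named genes are Hdac3, the 12 genes with the largest rises and the 12 with the largest falls among called genes whose arrays do not overlap between groups (leaving out predicted or clone names, small RNA genes, immune receptor segments and olfactory and vomeronasal receptors), and up to 4 called members of each list with the largest differences, or up to 2 with the smallest p where none passed. The rule was set before the data were examined. Not every gene that it picks is printed below, and genes named outside the rule are said where they occur.

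The fit was tested on simulated data for the comparison of knockout with rescued arrays, with 200 of 19933 genes changed. It recovered 51% of genes changed 1.3-fold, 98% of those changed 1.5-fold and 100% of those changed 2-fold, with 4, 11 and 6 false calls. The noise was drawn independently for each gene and array at the gene's moderated SD. It held no correlation between genes and no offset between arrays, unlike the real arrays. These numbers therefore test the fit and do not measure the recovery or false calls in the real comparison. For arrays, the number of samples limits the precision.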

Results

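Liver gene expression was measured on 7 Affymetrix Mouse Gene ST arrays, each hybridised with total RNA from the liver of a C57BL/6 male mouse aged 4 months. In the HDAC3 knockout group (3 arrays), mice received an adeno-associated virus that carries Cre recombinase. In the rescued group (4 arrays), they received the same Cre virus together with a virus that encodes Flag-tagged wild-type HDAC3. HDAC3 is a class I histone deacetylase that works within the NCoR and SMRT corepressor complexes. Mice had free access to chow, and livers were collected 2 weeks after injection at 5 pm, 10 h after lights on (ZT10). The comparison asks which liver transcripts differ when HDAC3 is missing from when it has been put back. The rescued mice differ from the knockout mice by an additional vector, and no array of an uninjected liver was analysed here. Values are log2 intensities as mean ± SD, and differences are knockout minus rescued. Arrays correlated at r = 0.994 to 0.995 across genes within the knockout group, at 0.996 to 0.997 within the rescued group and at 0.988 to 0.993 between groups. The number of arrays limits the precision.

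The Hdac3 transcript was lower in the knockout livers, at 8.92 ± 0.16 (SD, n = 3) against 9.40 ± 0.13 (SD, n = 4) in the rescued livers. The difference was -0.48 (SE 0.10), or 1.40-fold lower, with adjusted p = 0.0124 in limma's moderated test, and all 3 knockout values lay below all 4 rescued values. Without knockout replicate 1 the difference was -0.49 and the call was lost, with adjusted p = 0.050013. The labels do not say which exons are deleted, and the probe set could read the vector transcript as well as what remains of the endogenous one, so this value checks the labels only in part.

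Of 19933 genes tested, 320 differed by at least 1.5-fold at an adjusted p under 0.05, 163 of them higher and 157 lower in the knockout livers. By far the largest difference was the fall of Hsd3b5, a male-biased member of the 3-beta-hydroxysteroid dehydrogenase family. Its level was 5.59 ± 0.23 (SD, n = 3) in knockout and 11.21 ± 0.21 (SD, n = 4) in rescued livers, 49.0-fold lower (adjusted p = 1.58e-09). The knockout level lay at percentile 84.8 of 1194 olfactory and vomeronasal receptor genes, which are not expected to be expressed in liver, so it is not shown to be above background and the exact fold is uncertain. Hao1, which encodes the glycolate oxidase of peroxisomes, was 8.37-fold lower at 7.53 ± 0.42 against 10.60 ± 0.11 (adjusted p = 4.01e-06). The organic anion transporter Slco1a1 was 4.83-fold lower and Slc22a30, of the organic anion transporter family, 3.96-fold lower. The NADPH oxidase Nox4 fell by 1.82 on the log2 scale, 3.54-fold, with adjusted p = 9.97e-07. Next came Nrep (3.30-fold lower), the adhesion receptor gene Adgrf1 (3.29-fold), the complement regulator Susd4 (3.28-fold) and Zfp141 (3.26-fold, with a log2 difference of -0.90 at its other probe set). Nxpe2 was 3.06-fold lower, the hydroxyproline dehydrogenase gene Prodh2 2.86-fold and the alcohol dehydrogenase pseudogene Adh6-ps1 2.64-fold.

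The largest rise was that of Orm3, an orosomucoid gene of the acute phase family, from 7.88 ± 0.46 in rescued (SD, n = 4) to 10.02 ± 0.75 in knockout livers (SD, n = 3), 4.40-fold with adjusted p = 0.00285. Serpina7, which encodes thyroxine-binding globulin, was 3.80-fold higher (adjusted p = 0.000730). Cidec, a lipid droplet fusion protein gene, was 3.66-fold higher at 9.24 ± 1.195 against 7.37 ± 0.29 (adjusted p = 0.0177). Its knockout values were widely spread, the difference ranged from 1.33 to 2.51 with each array left out in turn, and the call was lost without knockout replicate 1 or rescued replicate 3. The immediate early factor Egr1 was 3.14-fold higher and the proton pump subunit Atp6v0d2 3.05-fold. The sulfotransferase Sult3a1 was also among the 12 largest rises, at 5.04 ± 0.89 against 3.51 ± 0.10. Both levels lay within the range of the receptor genes (percentiles 70.3 and 16.1), so no fold is given and its rank is uncertain. The monocarboxylate transporter family gene Slc16a5 rose 2.83-fold with little spread (adjusted p = 1.99e-05). Further rises were those of the efflux pump Abcc4 (2.69-fold), the magnesium transporter Slc41a2 (2.61-fold), the fatty acid hydroxylase Cyp4a14 (2.56-fold), the carbonic anhydrase Car14 (2.48-fold) and Cyp2c39 (2.44-fold). All 24 genes with the largest differences were called with the same sign as deposited and after quantile, median and cyclic loess scaling. Hsd3b5, Orm3, Sult3a1, Cyp4a14 and Cyp2c39 belong to multigene families, and their probes can cross-hybridise with close relatives.

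**Figure D1:**
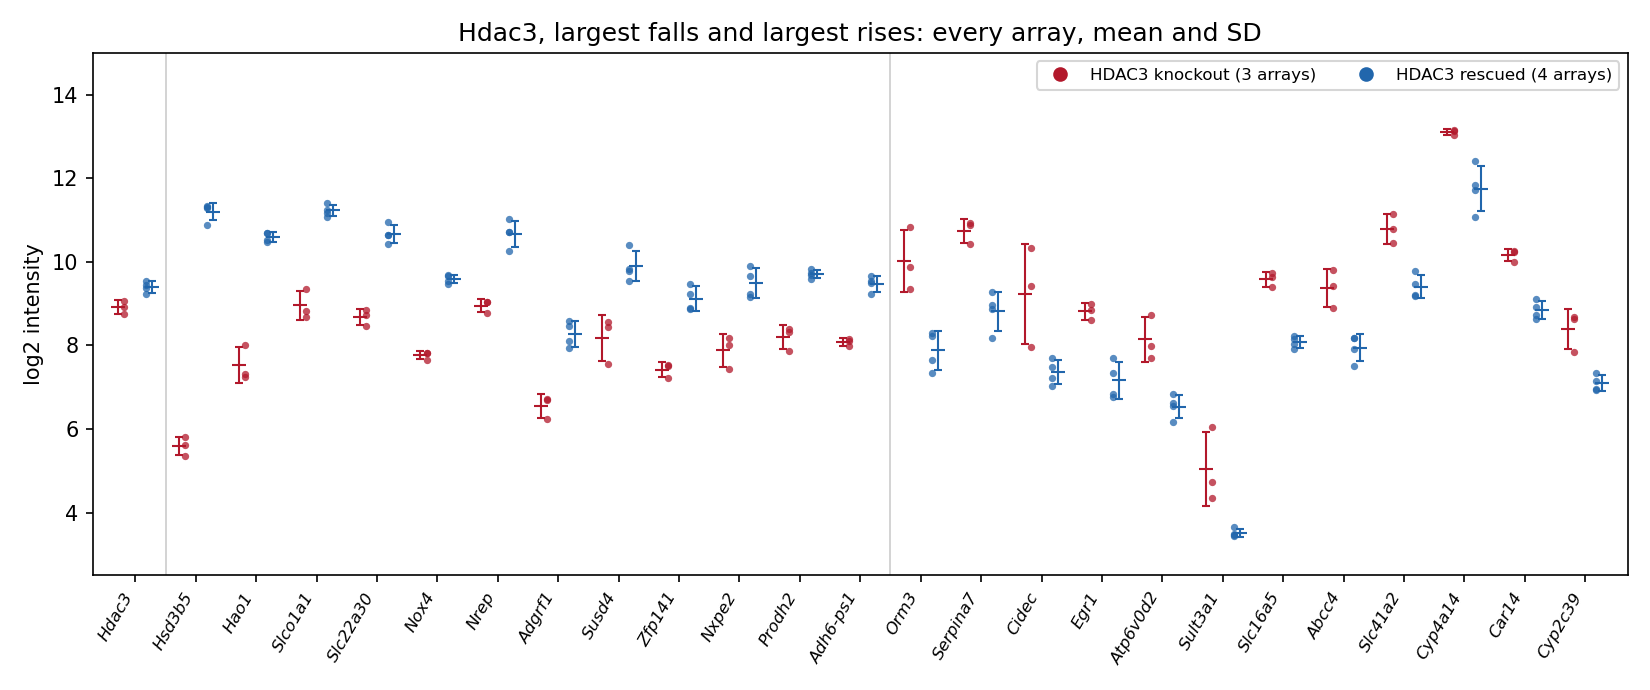
Log2 intensity of Hdac3, of the 12 genes with the largest falls and of the 12 with the largest rises, with a point for each array and bars for the mean ± SD of the 3 knockout (red) and 4 rescued (blue) arrays. The knockout arrays of Hsd3b5 average 5.59 against 11.21 in the rescued arrays, and Cidec shows the widest spread, with an SD of 1.195 in the knockout arrays.

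At any fold, 2867 genes passed an adjusted p under 0.05, 1901 higher and 966 lower in the knockout livers, so 66.3% of the calls were higher. This split depended on the scaling of the arrays. The share of higher calls was 45.9% after quantile normalization, 27.2% after median centring and 45.0% after cyclic loess. The excess lay among dim probe sets. Among genes below the median level, 995 were higher and 96 lower, with a median difference of 0.14, while above the median level 906 were higher and 870 lower. The genes called with the same sign as deposited and in all 3 scalings numbered 1330, 521 higher and 809 lower. Of these, 305 differed by at least 1.5-fold, 151 higher and 154 lower. At an unadjusted p under 0.05 there were 7115 genes, and the arrays of the groups did not overlap for 29.6% of genes, against 5.71% by chance. Both numbers are for the values as deposited, in which every knockout array had a higher median than every rescued array. Such an offset can separate the groups by itself, and the share was not computed after rescaling.

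**Figure D2:**
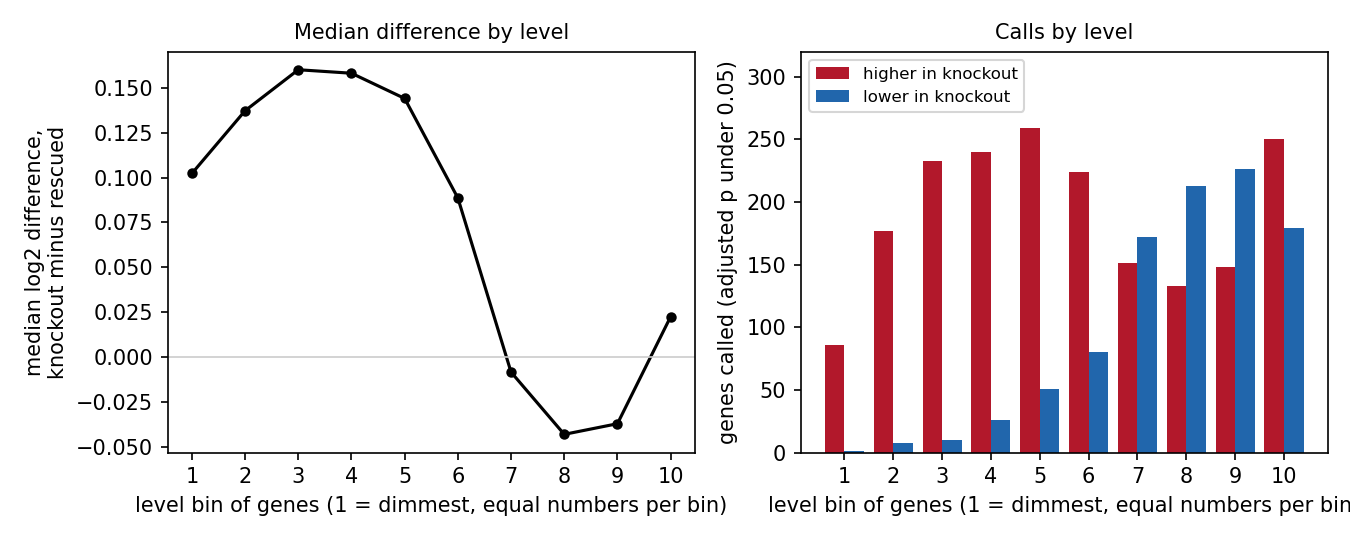
Left, median log2 difference (knockout minus rescued) of the genes in each of 10 equal bins by mean level. Right, number of genes called higher (red) or lower (blue) in knockout livers in each bin. The median reaches 0.16 among dim genes and lies near 0 or below it in bins 7 to 9, where calls in both directions are frequent.

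Gene lists fixed before the data were examined were compared with all other genes by limma's camera test, and 7 of 39 lists passed an adjusted p under 0.05. No list passed with the correlation between genes estimated per list. The count of 7 is also not shown to be beyond chance. Of the 35 splits of the 7 arrays, 20 gave as many lists, the real one included. The other splits mix knockout and rescued arrays and can keep part of the group difference, so they do not decide this. The groups below are therefore described by their numbers of called members. For a list that did not pass, the camera settings printed below are those in which it passed, unless said otherwise. In the other camera settings run list by list its adjusted p was 0.05 or more. Over all genes 14.4% were called, 9.54% higher and 4.85% lower, and no test compared the count of a list with these shares. Counts adjusted over the list alone apply Benjamini-Hochberg to the members only, and these shares are no measure for them. Of 19933 genes 7115 had an unadjusted p under 0.05 in limma's test, so such counts can be large for any list. They are given as values and not as further evidence for a list.

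PPAR alpha target genes of the fasting type were higher in the knockout livers, 9 of 15 measured members and none lower, and all 9 were called in every scaling. Adjusted over the list alone, 10 were higher. Cyp4a14 rose from 11.76 ± 0.55 to 13.11 ± 0.07, and Cyp4a31 was 2.02-fold higher, both in a family with closely similar members. The pyruvate dehydrogenase kinase Pdk4 was 2.30-fold higher (adjusted p = 0.00472) and the pantetheinase Vnn1 1.92-fold. The list passed camera with adjusted p = 0.00176, and adjusted p was 0.639 with an estimated correlation. Among 22 genes of fatty acid oxidation and ketogenesis, 9 were higher and 1 lower, and adjusted over the list alone 10 were higher and 1 lower. The lower member was the ketone body enzyme Bdh1, named outside the rule and not run with each array left out. In every scaling 7 were higher and 1 lower. The peroxisomal thiolase Acaa1b (2.17-fold) and the bifunctional enzyme Ehhadh (2.13-fold, adjusted p = 0.000285) led this group, with carnitine acetyltransferase Crat at 1.60-fold and Acaa1a at 1.49-fold. Acaa1a and Acaa1b are close paralogs. This list had adjusted p = 0.0355 in camera and 0.757 with an estimated correlation, and lost its call without knockout replicate 2 (0.167), rescued replicate 1 (0.130) or rescued replicate 2 (0.0534).

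Of 14 glycerolipid synthesis genes, 5 were higher and none lower, 4 in every scaling, or 10 adjusted over the list alone. The monoacylglycerol acyltransferase Mogat2 was 1.43-fold higher (adjusted p = 0.00275) and the glycerol phosphate acyltransferases Gpat3 and Gpam 1.40-fold and 1.65-fold. The call of Gpam was lost without knockout replicate 1 or 2 or rescued replicate 2, 3 or 4, with differences from 0.53 to 1.00. Camera gave adjusted p = 0.0251, and 0.757 with an estimated correlation; without knockout replicate 2 it was 0.0721 and without rescued replicate 4 it was 0.0589. Among 19 lipid droplet proteins, 7 were higher and 2 lower, 6 and 2 in every scaling, and adjusted over the list alone 8 and 2. The droplet coat protein Plin2 rose 1.91-fold, from 11.33 ± 0.13 to 12.27 ± 0.33, and Fitm1 1.66-fold, while the droplet-associated dehydrogenase Hsd17b11 was 1.68-fold lower. This list had adjusted p = 0.181, 0.0189 after quantile normalization, 0.0141 after cyclic loess and 0.0291 above the median level. Of 14 genes of PPAR gamma and its adipocyte-type targets, 5 were higher and none lower, 3 in every scaling, or 9 adjusted over the list alone. Besides Cidec these included the fatty acid transporter Cd36 (1.80-fold, adjusted p = 0.0103) and Anxa2 (1.41-fold), the latter lost without knockout replicate 1, with differences from 0.41 to 0.63. Apoa4 was another, with differences from 0.59 to 1.19. Its call was lost without knockout replicate 1 or 2 or rescued replicate 1, 2 or 3. Camera gave adjusted p = 0.0251 for this list, 0.757 with an estimated correlation and 0.128 without knockout replicate 2.

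Of 18 measured fatty acid synthesis genes, 5 were higher and none lower, 7 adjusted over the list alone and 2 in every scaling, and the list had adjusted p = 0.235, 0.0376 after cyclic loess and 0.0421 above the median level. The acetyl-CoA carboxylase Acacb was 2.08-fold higher, at 10.40 ± 0.14 against 9.34 ± 0.24 (adjusted p = 0.000822), and the elongase Elovl5 1.61-fold. Acss2 and Elovl6 were also called higher. With an array left out they kept their calls only without rescued replicate 1, with differences from 0.545 to 0.85 and from 0.28 to 0.44. Among 20 cholesterol synthesis genes 1 passed, the HMG-CoA synthase Hmgcs1, which was 1.99-fold higher (adjusted p = 0.0121) and was not called without knockout replicate 1, with differences from 0.86 to 1.16. Adjusted over the list alone the count was the same, and the list's adjusted p was 0.905. The lipoprotein list of 15 genes held 2 higher members, of which Tm6sf2 (1.53-fold) held in every scaling, and the same number adjusted over the list alone. Of 12 LXR targets 3 were higher and 1 lower, 1 and 1 in every scaling, or 4 and 1 adjusted over the list alone. The receptor gene Nr1h3 itself differed by -0.59 (adjusted p = 0.00163) and the phospholipid acyltransferase Lpcat3 by 0.38. Pltp, also called higher, ranged from 0.81 to 1.28 with an array left out. Its call was lost without knockout replicate 1 or 2 or rescued replicate 2. Of 19 sphingolipid genes 3 were higher and 2 lower, 1 and 1 in every scaling, 4 and 3 adjusted over the list alone, with the glucosylceramide synthase Ugcg 1.40-fold lower.

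Of 14 gluconeogenesis genes, 3 were lower and 2 higher, and adjusted over the list alone 4 were lower and 3 higher. The glucose-6-phosphatase gene G6pc was 2.16-fold lower, at 11.16 ± 0.54 against 12.27 ± 0.14 (adjusted p = 0.00691). The glycogen-targeting subunit Ppp1r3c was 1.97-fold lower and the glucose-6-phosphate transporter Slc37a4 1.26-fold. The lower 3 held in every scaling and the higher 2 did not. Of 14 glycolysis genes 3 were lower and 2 higher, likewise when adjusted over the list alone, and 2 and 1 in every scaling. Pfkfb3, which makes the activator of phosphofructokinase, was 1.73-fold lower and the glycerol phosphate dehydrogenase Gpd1 1.46-fold higher. Neither list passed camera (adjusted p = 0.228 and 0.345).

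Among 17 clock genes, 4 were higher and 1 lower, all in every scaling. The repressor Nfil3 was 1.95-fold higher (adjusted p = 0.00165), the nuclear receptor Nr1d1 1.69-fold, Arntl, which encodes BMAL1, 1.62-fold (adjusted p = 0.000736) and Clock 1.29-fold. Cry2, named after its value was seen as the one lower member, was at 8.40 in knockout and 8.74 in rescued livers. Adjusted over the list alone, 5 were higher and 7 lower, and camera gave adjusted p = 0.228. All livers came from 1 time of day.

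Of 14 male-biased genes, 5 were lower and 1 higher, all in every scaling, and adjusted over the list alone 6 were lower and 4 higher. The lower members were Hsd3b5, Slco1a1, Susd4, the oxysterol hydroxylase Cyp7b1 (2.16-fold lower) and, named after its value was seen, C8a. The higher member, also named after its value was seen, was the elongase gene Elovl3, with a log2 difference of 1.01. The median of the list was -0.13 and its mean -0.74, and camera gave adjusted p = 0.00382, or 0.639 with an estimated correlation. Of 16 female-biased genes, 7 were higher and none lower, 6 in every scaling and 8 adjusted over the list alone, with Sult3a1, Cyp4a14, Cyp17a1 (1.98-fold) and Cd36 ahead. The rank of Sult3a1 is uncertain, since both its levels lay within the range of the receptor genes. The call of Cyp17a1 was lost without knockout replicate 1 or rescued replicate 3, with differences from 0.81 to 1.21. Camera gave adjusted p = 0.0251 for the female-biased list and 0.639 with an estimated correlation; it was 0.0721 without knockout replicate 2, 0.0765 without knockout replicate 3 and 0.0604 without rescued replicate 1. Cyp4a14 and Cd36 are also members of the PPAR lists. All mice were male. The Y-linked genes Eif2s3y, Uty and Kdm5d, chosen after the values of the sex-biased lists were seen, differed by -0.48, -0.45 and -0.31. Each was called lower in limma's test (adjusted p = 0.00663, 0.0112 and 0.0205), also after cyclic loess (0.0113, 0.0165 and 0.0143). Xist, chosen likewise, differed by 0.23 (adjusted p = 0.0914), or 0.11 after cyclic loess (adjusted p = 0.369), at a level at percentile 8.21 of all genes.

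**Figure D3:**
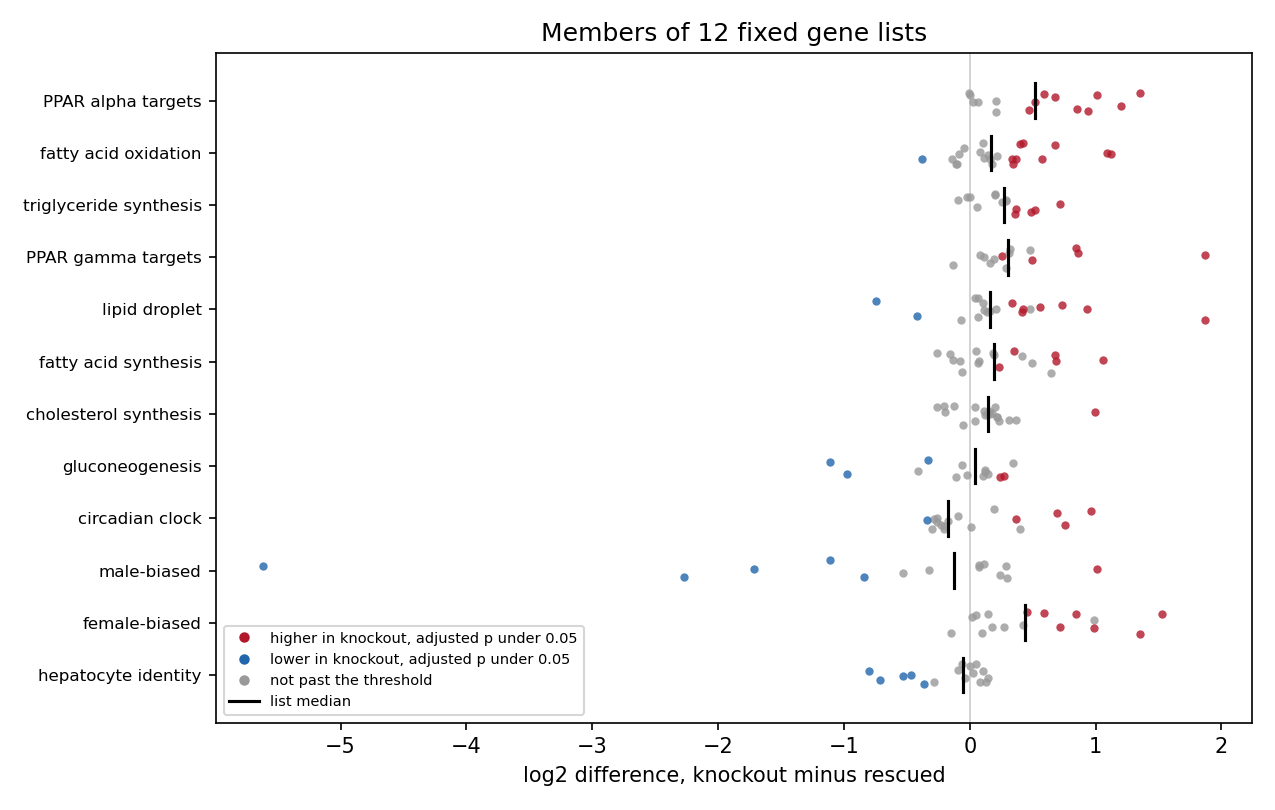
Log2 difference (knockout minus rescued) of each measured member of 12 fixed gene lists, red where called higher, blue where called lower, grey otherwise, with a black line at the list median. The PPAR alpha targets have 9 red points and no blue ones, and the male-biased list reaches -5.61 at Hsd3b5.

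Of 16 hepatocyte identity genes, 5 were lower and none higher, all in every scaling, and the count adjusted over the list alone was the same. The transcription factor genes Onecut1 (1.74-fold lower), Prox1 (1.64-fold) and Foxa3 (1.44-fold), the receptor gene Nr1h4 (1.29-fold) and the clotting factor gene F9 (1.38-fold) made up this group. The median of the list was -0.05. Camera gave adjusted p = 0.00603, 0.639 with an estimated correlation and 0.153 among genes above the median level. Onecut1 was not called without knockout replicate 1 or rescued replicate 3, Prox1 without knockout replicate 1 or 2, and Nr1h4 without knockout replicate 1 or rescued replicate 3. With an array left out, Onecut1 ranged from -0.95 to -0.57, Prox1 from -0.89 to -0.59 and Nr1h4 from -0.42 to -0.28. Of 14 pericentral genes 3 were higher and 2 lower, 2 and 2 in every scaling, 5 and 2 adjusted over the list alone. Ornithine aminotransferase Oat was 1.65-fold higher (adjusted p = 0.000285), and Lect2 1.45-fold lower. Of 12 periportal genes 1 was higher and 1 lower, with the lower one called in every scaling, and 3 and 1 adjusted over the list alone.

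Within the corepressor complex, 3 of 5 listed genes were measured and 1 was called, Tbl1xr1, which rose 2.30-fold from 9.24 ± 0.06 to 10.44 ± 0.09 (adjusted p = 1.69e-05). Its other probe set differed by 1.07. Adjusted over the list alone, 2 were higher. Of 10 other histone deacetylases, Hdac5 was 1.45-fold higher and Hdac2 1.39-fold lower, both in every scaling. Adjusted over the list alone, 1 was higher and 3 lower. The call of Hdac5 was lost without knockout replicate 1 or 2 or rescued replicate 2 or 3, and that of Hdac2 without knockout replicate 1 or 2, with differences from 0.44 to 0.68 and from -0.57 to -0.40.

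Of 13 NRF2 target genes, 6 were higher and 1 lower, 4 and 1 in every scaling, and adjusted over the list alone 7 and 2. The quinone reductase Nqo1 was 2.05-fold higher, the haem oxygenase Hmox1 1.57-fold higher and the carboxylesterase Ces2g 1.58-fold lower. This list had adjusted p = 0.130, 0.0083 after quantile normalization, 0.0188 after median centring, 0.00488 after cyclic loess, 0.0275 above the median level and 0.0111 without knockout replicate 3. It did not pass without knockout replicate 2 (0.297), without rescued replicate 1 (0.216) or with an estimated correlation (0.757). Of 15 drug-metabolising enzymes of the CAR, PXR and AhR programmes, 4 were higher and none lower, 2 in every scaling and 4 adjusted over the list alone, with the glutathione transferase Gstm3, of a multigene family, 1.83-fold higher. Their list had adjusted p = 0.143, 0.0420 with the replicate block, 0.0478 after median centring, 0.0295 after cyclic loess and 0.0275 above the median level. Of 19 bile acid genes 2 were higher and 2 lower, 4 and 3 adjusted over the list alone. Only the lower members, Cyp7b1 and the bile acid receptor gene Nr1h4, held in every scaling. The urea cycle and amino acid list of 17 held 2 higher and 2 lower members, 4 and 2 adjusted over the list alone, with ornithine transcarbamylase Otc 1.33-fold lower. Of 12 thyroid hormone receptor targets 2 were higher and 1 lower, all in every scaling, or 3 and 1 adjusted over the list alone.

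Of 20 acute phase genes 3 were higher, also when adjusted over the list alone, and Orm3 alone was called in every scaling. This list had adjusted p = 0.787 in camera and 0.0336 without knockout replicate 1. Its direction turned to lower without knockout replicate 3 (0.0934) or rescued replicate 1 (0.985). Of 18 interferon-stimulated genes 1 passed, Rsad2 at 1.36-fold, which held without rescued replicate 2 or 4 but not without any other array (differences from 0.35 to 0.54) and did not pass adjusted over the list alone. The stress response list of 19 held 2 higher and 1 lower members, 3 and 1 adjusted over the list alone, with Xbp1 1.35-fold lower, a call lost without knockout replicate 1 or 2 (differences from -0.49 to -0.34). Of 16 p53 targets 1 was higher, Btg2 at 1.85-fold, and likewise adjusted over the list alone. Of 23 cell cycle genes 3 were higher and 2 lower, the same adjusted over the list alone. Only the lower ones, Rrm2 (1.49-fold) and Ccne2 (1.41-fold), held in every scaling, and Ccne2 was lost without knockout replicate 1 or 3 or rescued replicate 2 or 3 (differences from -0.61 to -0.39). Both levels of Ccne2 lay within the range of the receptor genes (percentiles 83.6 and 93.3), so its fold is uncertain. None of 11 fetal liver genes and none of 22 nuclear-encoded respiratory chain genes passed limma's test, over all genes or adjusted over the list alone, and 4 and 2 of them had an unadjusted p under 0.05.

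Markers of other cells differed little. Of 19 macrophage markers 3 were higher, of 11 neutrophil markers 2, of 20 stellate and matrix genes 2 and of 17 lymphocyte markers 1, at 1.19-fold to 1.26-fold, and none of these was called in every scaling. Among them Mmp12, Ccr2 and Camp lay near or within the range of the receptor genes (knockout percentiles 93.2, 67.6 and 95.5). Adjusted over the list alone, the counts were 3, 2, 4 and 0. The macrophage list had adjusted p = 0.202 in camera, 0.0438 after quantile normalization, 0.0386 after cyclic loess and 0.0322 without rescued replicate 2. The neutrophil list had 0.0860, 0.0478 after median centring and 0.00645 without knockout replicate 1, and the stellate list 0.228 and 0.0421 above the median level. Of 16 endothelial markers 2 were lower, Clec4g and Fcgr2b, with none in every scaling or adjusted over the list alone. Clec4g was at -0.29 and its other probe set at 0.08. With an array left out, Clec4g kept its call only without knockout replicate 2, with differences from -0.37 to -0.19. Fcgr2b lost its call without each array in turn. The endothelial list had adjusted p = 0.181 and 0.0296 without knockout replicate 2. None of 11 bile duct markers and none of 9 adipocyte markers passed limma's test, over all genes or adjusted over the list alone, and 3 and 2 had an unadjusted p under 0.05. Of 13 pancreas, gut and muscle transcripts 2 were higher, or 5 adjusted over the list alone, with Cela2a at 1.28-fold, a call lost without knockout replicate 1 or rescued replicate 3 (differences from 0.30 to 0.42), and adjusted p for that list was 0.133, or 0.0490 after median centring. Of 3 measured red blood cell transcripts, Alas2 was 2.22-fold lower, from 9.56 ± 0.12 to 8.41 ± 0.21 (adjusted p = 0.000190). The median difference over all 119 of these markers was 0.15 as deposited and 0.06 after cyclic loess.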

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

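The tests of the sex-biased genes and of the cell markers, and the splits counted list by list, were chosen after those results were seen, as was the use of splits, receptor genes and single lists in judging the cell markers; the splits for the 5 main counts were planned, and the test on receptor genes was set before their values were seen but after the higher and lower split was.

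Among the rescued arrays, 9 of the 130 named genes had 1 array far from the other 3, where chance gives about 5% of genes. Hsd3b5 was at 10.90 in replicate 2 against 11.29 to 11.34 in the others. Cd36 was at 9.09 in replicate 1, above 8.70 to 8.76. Replicate 4 stood apart for Agpat3 (10.88, others 10.66 to 10.68), Ehhadh (11.40, others 11.05 to 11.09), Nfil3 (7.56, others 7.97 to 7.98) and Nr1d1 (10.001, others 10.32 to 10.38). Lin28b was at 4.53 in replicate 2 (others 4.58), Ndufa4 at 10.77 in replicate 3 (others 10.59 to 10.62) and Sphk1 at 6.59 in replicate 3 (others 6.76).

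All 35 splits of the 7 arrays into 3 and 4 were fitted. Only the real split reached the gene counts, which is the smallest share that 35 splits allow. The other splits mix knockout and rescued arrays, so a group difference widens their spread and lowers their counts. These splits therefore do not exclude chance by themselves. The 2867 called genes were reached by 1 split, the real one, and the highest other gave 2. For the 1901 higher genes the number was 1 and the highest other 2, for the 966 lower genes 1 and the highest other 1, and for the 320 genes of at least 1.5-fold 1 and the highest other 2. Chance cannot be excluded for the number of gene lists, since 20 of the 35 splits, the real one included, gave at least 7. The highest other gave 15. The mixed splits can keep part of the group difference, so they do not show that chance gives such counts either. List by list, with the real split included, a camera p as small came from 1 of 35 splits for the male-biased list, 3 each for PPAR alpha targets and triglyceride synthesis, 5 for hepatocyte identity, 6 for PPAR gamma targets, 9 for female-biased genes and 10 for fatty acid oxidation. A median as large came from the real split alone for PPAR alpha and PPAR gamma targets, triglyceride synthesis, fatty acid oxidation and female-biased genes. The same held for lists that did not pass the set test: clock, cell cycle, drug-metabolising enzymes, urea cycle and amino acids, neutrophil and lymphocyte markers. These medians are of the values as deposited, without the offset between the arrays taken out. Every knockout array had a higher median intensity than every rescued array, so the offset favours a large positive list median in the real split. For hepatocyte identity a median as large came from 4 splits, and for the male-biased list from 14.

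More genes were called higher than lower, 66.3% of the calls. An offset of dim probe sets left by the normalization may account for this excess, and the even split after cyclic loess does not bear on it, since that scaling centres genes at each level. The test was on 1194 olfactory and vomeronasal receptor genes, which are not expected to be expressed in liver and have a median level of 4.37. Their median difference was 0.12364, with 90.0% above 0, against 0.103 to 0.116 for the middle 95% of 10000 lists of other genes matched on level, so genes that should be silent were shifted slightly more than others of their level. No biological explanation was tested, and what put the offset into the deposited values stays open, including RNA quality, for which no measure was used here.

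In the knockout livers, all of male mice, 5 of 14 male-biased genes were called lower and 1 higher, and 7 of 16 female-biased genes were called higher. For the 5 male-biased genes called lower, with a median of -1.71, RNA of female livers is argued against as the whole cause, since the Y-linked genes, which it would lower at least as much, had a median of -0.45189; their own fall was not explained by any test here, and Xist, which such RNA would raise, differed by 0.23 without a call (adjusted p = 0.0914) but is too dim to exclude a share. For the same 5 genes, a lower share of hepatocyte RNA (list median -0.050033) and the scaling of the arrays (median -1.6855 after cyclic loess) are argued against as the whole cause. These genes were picked by their calls, and against the median of the whole male-biased list, -0.13, neither the Y-linked nor the hepatocyte median excludes anything. Hsd3b5 alone did not carry the list in camera (p = 0.0075213 without it, or 0.123 with an estimated correlation), but the remaining members have a median of 0.07 and a mean of -0.36, so a few genes carry it; a biological difference through HDAC3 stays a hypothesis.

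Markers of other cells were slightly higher, with a median of 0.15 over all 9 lists, used in place of a first choice of 5 made after their medians were seen. The lists differed: against 10000 random lists matched on level, macrophage, neutrophil, other organ and stellate markers lay at percentiles 98.8, 97.4, 96.4 and 95.6, adipocyte and lymphocyte markers at 78.2 and 76.0, and endothelial, blood and bile duct markers at 60.5, 52.7 and 23.3. Neither the offset of dim probe sets nor more RNA of these cells is excluded or shown. All lists together lay at percentile 99.7, and at 99.96 after cyclic loess, but receptor genes not expected in liver also lay at 99.99 and 100, the random lists take genes as independent, and 2 of the 35 splits gave a median as large as deposited, against 1 after loess. After loess macrophage markers lay at percentile 100 and bile duct, blood and endothelial markers at 17.6, 29.5 and 49.5; a lower share of hepatocytes, with 5 of 16 hepatocyte identity genes lower, stays open too.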

How the results depend on the processing

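No named gene changed sign in the alternatives run gene by gene, which leave out the filter joined with cyclic loess. The 2 filters, all rows, and trend and robust spread leave a gene's difference unchanged by construction. Only 114 of the 129 named genes other than Hdac3 lay above the median level. Genes of at least 1.5-fold numbered from 254 to 377 with an array left out. They numbered from 305 to 360 with the arrays rescaled or the same sign required in every scaling. Over all rows the count was 399 probe sets, with rows of several symbols or none among them, so it is not a count of genes. The count at 1.5-fold was not run at other thresholds, with treat or with the filter joined with cyclic loess. The number of called genes was 509 at an adjusted p under 0.01, 5528 under 0.10, 136 with treat against a fold of 1.2 and 1330 when the same sign was required in every scaling, and ranged from 897 (without knockout replicate 1) to 3263 (without rescued replicate 1) with each array left out in turn. It was 1721 without knockout replicate 2, and 1200, 948 and 1331 without rescued replicates 2, 3 and 4. Higher genes numbered 899 after quantile normalization, 672 after median centring, 873 after cyclic loess, 1032 above the median level, 1030 there after cyclic loess and 521 in every scaling, and from 449 to 2199 with an array left out. Lower genes numbered 1801 after median centring and from 417 to 1064 with an array left out. The lists past the set test numbered 11 after median centring, 12 after cyclic loess, 11 above the median level, 0 with an estimated correlation and 14 with fry (34 for change in either direction), and from 4 to 9 with an array left out. A stricter threshold lowers a count and a looser one raises it by construction, and for the other settings the cause was not tested. The difference of Hdac3 ranged from -0.56 to -0.40 with an array left out. Of 129 other named genes, 121 were called, 65 kept their call without each array in turn and 56 lost it without at least 1; quantile, median and cyclic loess scaling lost 23, 28 and 22. The requirement of every scaling and the filter joined with cyclic loess were chosen after seeing the data.

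The replicate numbers did not pair the samples, as same-numbered deviations correlated at 0.15, 0.0028 and 0.0053. Of the same-numbered arrays only those numbered 1 were each other's best partners. Knockout replicate 2 and rescued replicate 3 were best partners, as were knockout replicate 3 and rescued replicate 2. With the number as a replicate block, 1938 genes were called, 1233 higher and 705 lower, 322 of at least 1.5-fold, with 7 lists (adjusted p = 0.0564 for triglyceride synthesis) and a Hdac3 difference of -0.49. Arrays carry no background measure here, so how far dim genes lie above background limits the small rises.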

Other observations

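The tests of immediate early and growth hormone genes were set before the values of their further members were seen; the genes named in this paragraph were chosen after their values were seen. The genes Akr1c20, Akr1c14, Hsd3b2, Hsd3b3 and Hsd17b6, picked without a list or a test of enrichment, were lower in the knockout livers in every scaling, with log2 differences of -1.19 for Akr1c20, -0.997 for Akr1c14, -0.90 for Hsd3b2, -0.53 for Hsd3b3 and -0.82 for Hsd17b6, while the steroid hydroxylase gene Cyp17a1 was higher by 0.99. Genes within the Akr1c family are close relatives, as are those within the Hsd3b family, so part of these values can be cross-hybridisation. The complement genes C8a and C8b were lower by -0.84 and -0.76, and the clotting factor gene F11 by -0.73.

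Egr1, Btg2 and Atf3 were higher in the knockout livers, which may reflect a general immediate early response at tissue collection. The test was on 13 other immediate early genes. Their median difference was 0.25673, with 5 higher (Fos, Junb, Egr2, Zfp36 and Klf6) and none lower, and Junb alone was called in every scaling. The set test gave p = 0.0135, or 0.117 with an estimated correlation. The median lies below the 0.5 set beforehand for such a response and just above the 0.25 set for excluding it, so the test does not decide. This median is of the values as deposited. In these, all genes at mean levels of 5.98 to 6.42, where some of the 13 lie, had a median difference of 0.158. The offset may account for part of the 0.25673, and the median was not computed after rescaling.

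Socs2 was 0.409 times its rescued level (difference -1.29), and with the falls of Hsd3b5 and Slco1a1 this could come from lower growth hormone and STAT5 signalling. The test asked whether Cish and Igfals were lower and Bcl6 higher, and 0 of the 3 was called in its predicted direction. Cish differed by 0.20, Igfals by -0.09 and Bcl6 by -0.55, none past the threshold, so the hypothesis is neither borne out nor excluded. Stat5b itself was 1.68-fold higher (adjusted p = 0.00122) and the growth hormone receptor gene Ghr differed by -0.20 (adjusted p = 0.0473).

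Probe sets outside the gene comparison also differed. Among rows without a symbol, 397 of 4593 were called, 39 with at least 1.5-fold, and among rows with several symbols 119 of 1317, 26 with at least 1.5-fold.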
